A study of Homo sapiens with 2 samples.

How the data were processed

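The data were RNA-seq gene tables from 2 libraries of A549 cells, an established human lung adenocarcinoma line. One library came from cells labelled as the control for overexpression and the other from cells labelled as overexpressing PGC-1α, the transcriptional coactivator encoded by PPARGC1A. The labels describe culture under standard conditions, TRIzol extraction of total RNA and Illumina library preparation. They give no strand setting, no construct and no time after transfer of the gene. Each group held 1 library, so no difference below has a replicate check.

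The deposited tables held, per the file headers, a raw count for each of 58302 Ensembl genes, with the gene's symbol, coordinates, strand, length and biotype, and a separate FPKM value for each gene. Bowtie2 2.0.6, TopHat2 2.0.9, Cufflinks 2.1.1 and Cuffdiff 2.1.1 are named, per the submitters' processing notes, without a role for any of them. The program that made the counts, the genome build and the annotation are not given in the sources used here. Start and end equalled those of GENCODE release 29 on GRCh38 for 56636 of the 58039 gene identifiers present in both, or 97.6%, so coordinates below are given as the files list them and read as GRCh38. Gene symbols are those of the files, including older ones such as ATP5B and CTGF.

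The authors' FPKM values were checked against the deposited counts. In each library, count divided by the product of gene length and FPKM, times a fixed constant of the unit, gave a single library size, 27089164 for the control and 24367036 for the PGC-1α library. This held for all 25852 and all 25858 genes above 0, within a relative tolerance of 1e-06. Both sizes equalled those that DESeq2's median-of-ratios size factors gave when recomputed from these libraries. The FPKM values are therefore a rescaling of the same counts and not a separate measurement, and the DESeq2 alternative below uses the same scaling as the FPKM.

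Counts were analysed as deposited. Every row named a gene, and no column of another sample was present. Library totals were 27125084 counts for the control and 24334768 for the PGC-1α library, and TMM factors from edgeR 4.0.16 in R 4.3.3 were 1.01 and 0.995. A count of 3, taken as the limit that a count of 0 allows, corresponded to 0.110 and 0.124 CPM, where CPM is the count scaled to the TMM-normalised library size. Genes with a mean of at least 1 CPM over the 2 libraries were treated as measured. Log2 ratios of the PGC-1α library over the control were computed from TMM-normalised counts after adding 0.5 to each count. Exact 95% intervals came from the Clopper-Pearson interval of the split of the 2 counts. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules and differences between cultures are not included. The quasi-likelihood test of edgeR could not be fitted, because 1 library per group leaves no residual degrees of freedom, and no p-value is given. A gene was called higher or lower when its normalised counts differed at least 2-fold and its interval excluded a ratio of 1; within gene lists the threshold was 1.5-fold. Scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

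The grouping, the calls, the rule for named genes, 34 gene lists and the first set of alternatives were set before the data were examined. Named genes were PPARGC1A, FOXM1 and MUC1, the genes of the series title. To these were added the 10 protein-coding genes with the highest lower bound and the 10 with the lowest upper bound of the interval, among those with a mean of at least 5 CPM. In each list, up to 4 members with the highest absolute log2 ratio whose interval excluded 0 were named, or the most expressed members where none was 1.5-fold apart, together with all called members where these were 5 or fewer. Some genes that this rule takes are not reported here by name.

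Mitochondrial biogenesis factors were listed together with partner transcription factors of PGC-1 and without PPARGC1A. The tricarboxylic acid (TCA) cycle list also held pyruvate dehydrogenase genes. Gluconeogenic genes were listed together with other hepatic targets of PGC-1α and HNF4A. The other lists covered nuclear-encoded respiratory chain subunits, protein-coding genes of the mitochondrial genome, fatty acid oxidation, antioxidant genes linked to PGC-1α, mitochondrial ribosomal proteins, glycolysis and hypoxia-inducible genes. They also covered FOXM1 targets, replication genes, p53 targets, mucins and secretory genes, epithelial-mesenchymal transition, TGF-β targets, YAP targets, immediate-early genes, NRF2 targets, cholesterol synthesis, lipogenesis, interferon-stimulated genes, NF-κB targets, ATF4 targets, the unfolded protein response and heat shock. The remaining lists held cytosolic ribosomal proteins, replication histones, housekeeping genes, alveolar and airway genes, and markers of fibroblasts, immune cells, endothelial cells and the HEK293 line. A further 8 lists, used only in the closing section, were composed after values had been seen: the malate-aspartate shuttle, mitochondrial protein import, branched-chain amino acid catabolism, respiratory chain assembly factors, mitochondrial carriers, creatine metabolism, epithelial junctions and REST targets. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these 2 libraries. List entries under newer symbols were matched to the files through a table of gene identifiers and symbols. That lookup was completed after values had been seen and added 1 measured gene, HIST2H2AC, to the replication histones. Genes of a pathway are co-regulated and are not replicates. The interval given with a median is a 95% order-statistic interval over its members.

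Alternatives chosen before the data were examined were DESeq2 1.42.0 size factors, total-count scaling, upper-quartile scaling, no filter on low counts, a mean of at least 5 CPM, 5 counts added to each library, the authors' FPKM with a pseudocount of 0.1 or of 1 over genes with a mean FPKM of at least 1, an assumed biological coefficient of variation of 0.2 per library, protein-coding genes alone, and random lists matched on gene length in 5 bins within each expression bin. Chosen after seeing the data were a coefficient of variation of 0.4, a 4-fold threshold, the FPKM over the genes measured by CPM, the replication histones without HIST2H2AC, summed counts of near-identical copies, and random lists matched on transcript GC content. Copies were found by aligning the longest GENCODE 29 transcripts to each other with minimap2 2.31-r1302 and keeping pairs at least 98% identical over at least 50% of the length. Genes called at 2-fold that have such a copy are reported as uncertain, because the authors' counting could split reads between copies. List members called only at 1.5-fold are not marked for copies, although 490 measured genes have one. Genes whose coordinates overlap another measured gene are also uncertain, since no strand setting is stated.

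The procedure for the 2-fold calls was tested on simulated counts drawn from the means and depths of these libraries. The simulation compared control with overexpression, with 200 genes changed by known folds. The 1.5-fold calls within lists and the list percentiles were not simulated. Of the simulated genes 14175 passed the filter, 198 of the changed ones among them. The procedure called 75 of 75 genes changed 3-fold, 75 of 75 changed 6-fold, 1 of 50 changed 1.5-fold and 5 of 13977 unchanged genes. Intervals held the true ratio for 95.3% of unchanged genes. The simulation drew counting error alone, so these shares do not cover variation between cultures.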

Results

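Gene expression was measured by RNA-seq in A549 cells, a human lung adenocarcinoma line, with and without overexpression of PGC-1α, a coactivator known for driving mitochondrial genes. The comparison addressed which genes differ when PGC-1α is raised, and the series title names FOXM1, a transcription factor of dividing cells, and MUC1, a membrane-bound mucin. One library was sequenced per condition, with 27125084 counts in the control and 24334768 in the PGC-1α library. Counts above 0 were recorded for 25852 and 25858 of 58302 listed genes. With 1 library per group, the differences have no replicate check; ratios describe these 2 libraries, and their 95% intervals cover counting error only.

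PPARGC1A, the gene encoding PGC-1α (ENSG00000109819, chromosome 4, 23755041 to 23904089), had 5 counts in the control and 4654 in the PGC-1α library. This corresponded to 0.183 and 192 CPM and to a log2 ratio of 9.90 (8.81 to 11.66), so the library labels matched the level of the introduced gene. Counts per gene do not separate an introduced sequence from the cell's own transcript. The size of this ratio depended on the few control counts, and with the authors' FPKM the log2 ratio was 7.24 with a pseudocount of 0.1 and 4.19 with a pseudocount of 1.

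FOXM1 (ENSG00000111206, chromosome 12, 2857681 to 2877155) differed little, with 96.3 CPM in the control and 102 CPM in the PGC-1α library and a log2 ratio of 0.08 (-0.003 to 0.16). Its coordinates overlap ITFG2 and RHNO1 on the opposite strand. MUC1 (ENSG00000185499, chromosome 1, 155185824 to 155192916) was low in both libraries, with 52 counts in the control and 64 in the PGC-1α library. Its levels were 1.91 and 2.64 CPM and its log2 ratio was 0.47 (-0.08 to 1.03). A difference in MUC1 was therefore not detectable at this depth, and the interval allowed values from slightly lower to about 2-fold higher.

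Of 14154 measured genes, 248 were at least 2-fold higher in the PGC-1α library and 164 at least 2-fold lower, of which 209 and 121 were protein-coding. At least 4-fold differences were seen for 39 higher and 16 lower genes. Most genes lay close together, with 90.0% within 1.5-fold and a central range of log2 ratios from -0.54 at the 5th percentile to 0.63 at the 95th. The counts of called genes depended on the low-count filter: without one they were 789 and 486, and with a mean of at least 5 CPM they were 104 and 53. If an assumed biological coefficient of variation of 0.4 per library was added to the counting error, 61 higher and 28 lower genes were left. Of 175 genes ranked or called within lists, 49 overlap another measured gene and 24 a more abundant one, which leaves their counts uncertain without a strand setting. Of those named here, these 24 include FOSB, NPY4R, MT-ATP8, ESRRA, DECR1, ACADM, ALDOC, EGLN3, CA9, DDIT3, IFIT1, IFIT2 and IFIT3.

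**Figure D1:**
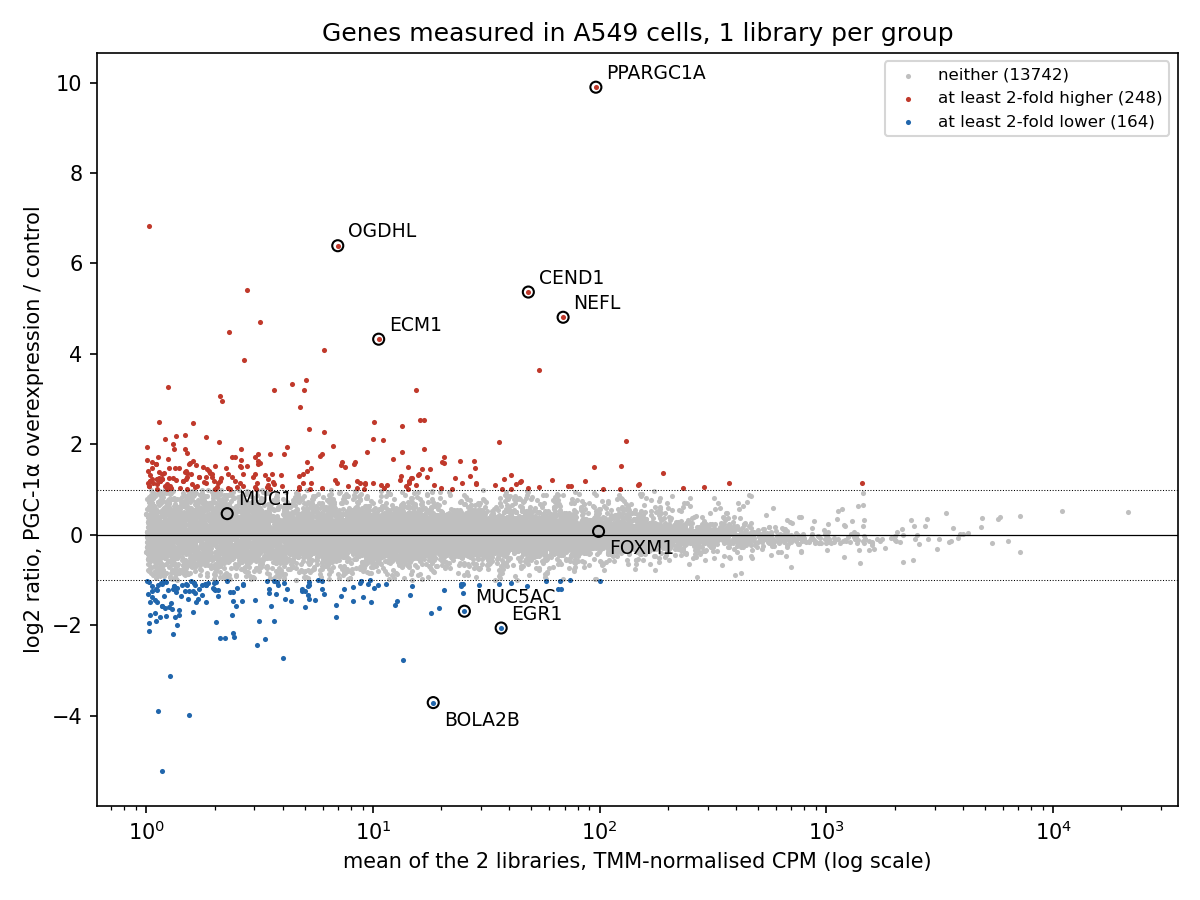
Log2 ratio of the PGC-1α library over the control library against the mean TMM-normalised CPM of the 2 libraries on a log axis, for the 14154 measured genes, 1 library per group. Red points are the 248 genes called higher, blue points the 164 called lower, grey points neither, dotted lines mark 2-fold, and PPARGC1A lies highest at 9.90 while FOXM1 lies at 0.08.

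After PPARGC1A itself, the highest-ranked protein-coding genes included OGDHL, CEND1 and NEFL. OGDHL, which encodes a 2-oxoglutarate dehydrogenase-like protein of mitochondria, had 4 counts in the control and 335 in the PGC-1α library, a log2 ratio of 6.39 (5.19 to 8.44). CEND1, linked to cell cycle exit of neuronal precursors, stood at 2.27 CPM in the control and 94.7 CPM in the PGC-1α library, a log2 ratio of 5.37 (5.02 to 5.77). NEFL, the neurofilament light chain gene, stood at 4.73 and 133 CPM, a log2 ratio of 4.81 (4.56 to 5.08). CACNB4, a voltage-gated calcium channel subunit gene, had a log2 ratio of 4.09 (3.44 to 4.90). Other genes chosen by this rank were the matrix protein gene ECM1 at 4.33, the Wnt ligand gene WNT11 at 3.43, WIPF3 at 3.20 and the transcription factor gene TFCP2L1 at 2.54. The FPKM scale lowered the ratios of the genes with few control counts, to 4.31 for OGDHL and 1.81 for CACNB4 with a pseudocount of 0.1.

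Among the lowest-ranked protein-coding genes, EGR1, an immediate-early transcription factor gene, stood at 59.3 CPM in the control and 14.2 CPM in the PGC-1α library, a log2 ratio of -2.06 (-2.23 to -1.89). FOSB, of the same class, had a log2 ratio of -1.47 (-1.74 to -1.22), with ERCC1 overlapping it on the opposite strand. MUC5AC, a gel-forming mucin gene, had 1054 counts in the control and 290 in the PGC-1α library, a log2 ratio of -1.69 (-1.88 to -1.50). CYP4F11, a cytochrome P450 gene, stood at -1.81, DKK3 at -1.63, KIAA0513 at -1.55 and C1orf116 at -1.54. The rank also took BOLA2B at -3.71, NPY4R at -1.73 and BX088645.1 at -1.49, which are uncertain because each has a near-identical copy. With the copies summed, BOLA2B and its copy had 940 and 80 counts, a log2 ratio of -3.37, and NPY4R and its copy had 1080 and 306, a log2 ratio of -1.65. The set holding BX088645.1 had 2347 and 1466 counts and a log2 ratio of -0.51, under 2-fold.

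Many genes of mitochondrial respiration were higher in the PGC-1α library. Of 75 nuclear-encoded subunits of the respiratory chain and ATP synthase, 39 were at least 1.5-fold higher, none were 1.5-fold lower and 36 were neither. Their median log2 ratio of 0.60 (0.50 to 0.64) exceeded the medians of all 10000 random lists. ATP5B, a catalytic subunit of ATP synthase, had 24235 counts in the control and 47861 in the PGC-1α library, a log2 ratio of 1.15, and ATP5G3 of the same enzyme stood at 1.14. COX7B and NDUFB9, subunits of complexes IV and I, both stood at 1.11. Genes were assigned to complexes by their symbols, which put NDUFA4, at 0.60, in complex I. By this grouping all 10 measured complex IV genes passed 1.5-fold, with a median of 0.82. Of 36 complex I genes 13 did, with a median of 0.42. Complex III had 5 of 9 genes past 1.5-fold, complex II 3 of 4, ATP synthase 7 of 15, and CYCS, encoding cytochrome c, stood at 0.87. NDUFV2 at -0.44 and NDUFC2 at -0.04, named after their values were seen, were the members below 0.

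Transcripts of the mitochondrial genome were a larger part of the PGC-1α library, at 8.32% of counts against 6.22% in the control, and mitochondrial rRNA took 1.42% against 0.992%. All 13 mitochondrially encoded protein genes had ratios above 1, with a median log2 ratio of 0.37 (0.22 to 0.52) above all 10000 random lists. Only MT-ATP8 passed 1.5-fold, at 0.78, and it overlaps the more abundant MT-ATP6. MT-ND6 stood at 0.53, MT-CO1 at 0.52 and MT-ND5 at 0.47.

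In the TCA cycle list, 9 of 20 genes were at least 1.5-fold higher and none lower. The list and this count also take in pyruvate dehydrogenase genes. Its median log2 ratio was 0.55 (0.38 to 0.97), above all 10000 random lists. The isocitrate dehydrogenase subunit gene IDH3A had a log2 ratio of 1.52 (1.44 to 1.60), the citrate synthase gene CS of 1.05 and the pyruvate dehydrogenase subunit gene PDHA1 of 1.04. SDHA and SDHB belong to this list and to the respiratory chain list. For fatty acid oxidation, 6 of 23 genes were higher and 1 lower, and the median of 0.31 (0.10 to 0.48) again lay above all 10000 random lists. DECR1 stood at 1.06, UCP3 at 1.05, ACADS at 0.95 and ACADM at 0.88, while CPT1C stood at -0.59. DECR1 and ACADM overlap NBN and RABGGTB, which are more abundant and stood at -0.03 and -0.18. Mitochondrial ribosomal proteins had 3 of 46 genes higher, MRPL2 at 0.96, MRPS5 at 0.91 and MRPS25 at 0.91, and a median of 0.19 (0.10 to 0.26), above all 10000 random lists.

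The list of mitochondrial biogenesis factors and PGC-1 partner transcription factors, which does not hold PPARGC1A, showed no shift as a group. Of 21 measured genes, 1 was 1.5-fold higher, ESRRA, the nuclear receptor ERRα, at 0.71 (0.63 to 0.79), and none were lower. The list's median was 0.02, at percentile 65.3. PPARG stood at -0.40, PPARA at 0.37 and PPARGC1B at -0.36, all under 1.5-fold. Of 12 antioxidant genes linked to PGC-1α, SOD2, the mitochondrial superoxide dismutase gene, was higher at 0.81 (0.75 to 0.87), the other 11 were under 1.5-fold, and the median was 0.17 at percentile 99.7.

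Some glycolytic and hypoxia-inducible genes were also higher, while most members of both lists were under 1.5-fold. For glycolysis, 7 of 21 genes were at least 1.5-fold higher and none lower, with a median log2 ratio of 0.31 (0.06 to 0.65) above all 10000 random lists. GPI stood at 0.93, PFKM at 0.82, ALDOC at 0.69 and HK1 at 0.68. Among 22 hypoxia-inducible genes, 9 were higher and none lower, with a median of 0.28 (0.07 to 0.71) above all 10000 random lists. With a mean of at least 5 CPM their median was 0.15. The prolyl hydroxylase gene EGLN3 had a log2 ratio of 1.73 (1.53 to 1.94), the glucose transporter gene SLC2A3 of 1.23, ANGPTL4 of 1.03 and CA9 of 0.92. Other hypoxia-inducible genes stayed near 0, such as SLC2A1 at -0.07 and NDRG1 at -0.18, which were picked after their values were seen. Of 17 gluconeogenic genes and other hepatic targets of PGC-1α and HNF4A, 6 were measured. The gluconeogenic genes PCK1, G6PC1 and FBP1 were not among them. In this mixed list IGFBP1 was higher at 1.01, and the median of -0.11 lay at percentile 14.4 with a mean of 0.03.

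Proliferation genes differed little between the libraries. None of 32 FOXM1 targets, genes of mitosis and its entry, was 1.5-fold apart, and their median log2 ratio was -0.01 (-0.12 to 0.04), at percentile 63.3. The most expressed of them were TOP2A at -0.10, MKI67 at 0.02, CDC25B at -0.05 and TPX2 at 0.01. Of 28 genes of replication and its onset, 1 was higher, the cyclin gene CCNE1 at 0.86 (0.73 to 0.99), and the median was -0.03 at percentile 34.9, with a mean of 0.03. Among 22 p53 targets, SESN1 at 0.75 and BTG2 at 0.61 were higher, none were lower, and the median of 0.23 (0.12 to 0.39) exceeded those of 9999 random lists.

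Mucins and secretory genes differed in both directions. Of 22 listed, 9 were measured, 4 were at least 1.5-fold lower and 1 was higher. SPDEF, a transcription factor of secretory cells, stood at 152 and 27 counts, a log2 ratio of -2.30 (-2.97 to -1.72). MUC5AC stood at -1.69, and MUC5B and AGR2, a protein disulfide isomerase gene of mucus cells, both stood at -1.19. TFF1, a trefoil peptide gene, was higher at 3.06 (2.24 to 4.11), with 12 counts in the control and 92 in the PGC-1α library. The list's median of -0.19 lay at percentile 7.28. With a mean of at least 5 CPM the median was -1.19, but that filter drops SPDEF, MUC1 and the only higher gene, TFF1. Among 23 genes of epithelial-mesenchymal transition, 5 were lower and 1 higher. The lower ones were ZEB2 at -0.98, CDH1 at -0.95, SPARC at -0.85, CLDN4 at -0.76 and MMP2 at -0.69, and COL1A1 was higher at 0.66. These members include both epithelial genes, such as CDH1, and mesenchymal ones, such as ZEB2. Their median of 0.19 (-0.24 to 0.28) lay at percentile 99.9 while their mean was -0.04, so the list gives no single direction.

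Several signalling and lipid lists had medians below 0, although most of their members were under 1.5-fold. Of 22 immediate-early genes, 8 were at least 1.5-fold lower and none higher, with a median log2 ratio of -0.40 (-0.84 to -0.13) below all 10000 random lists. Besides EGR1 and FOSB, CTGF stood at -0.91 and FOS at -0.88. Among 14 YAP targets, ANKRD1 at -1.94 (-2.74 to -1.25) and CTGF were lower, none were higher, and the median of -0.41 (-0.54 to -0.03) lay below all 10000 random lists. CTGF and CYR61 belong to both lists. For cholesterol synthesis, 5 of 24 genes were lower, among them INSIG1 at -0.74, LSS at -0.73 and HSD17B7 at -0.69. None was higher, 23 of the 24 had ratios under 1, and the median was -0.35 (-0.55 to -0.23), below all 10000 random lists. In lipogenesis, FADS2 at -0.85 and SCD at -0.62 were lower and ACACB was higher at 0.72, and the other 16 of 19 genes were neither. The median of -0.20 lay at percentile 0.02, and its interval of -0.43 to 0.15 included 0. The genes FADS1 and FADS2 overlap in the files.

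NRF2 targets, genes of the oxidative stress response, had 3 of 25 members lower and none higher, with a median of -0.31 (-0.37 to -0.18) below all 10000 random lists. AKR1C1 stood at -0.72, AKR1B10 at -0.60 and EPHX1 at -0.60, and AKR1C3 at -0.49 was under 1.5-fold. Cytosolic ribosomal protein genes were shifted slightly down as a group, with none of 68 past 1.5-fold and a median of -0.10 (-0.13 to -0.08) at percentile 0.16. The most expressed were RPL13A at -0.10, RPS16 at 0.06, RPS19 at -0.03 and RPL4 at -0.13.

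**Figure D2:**
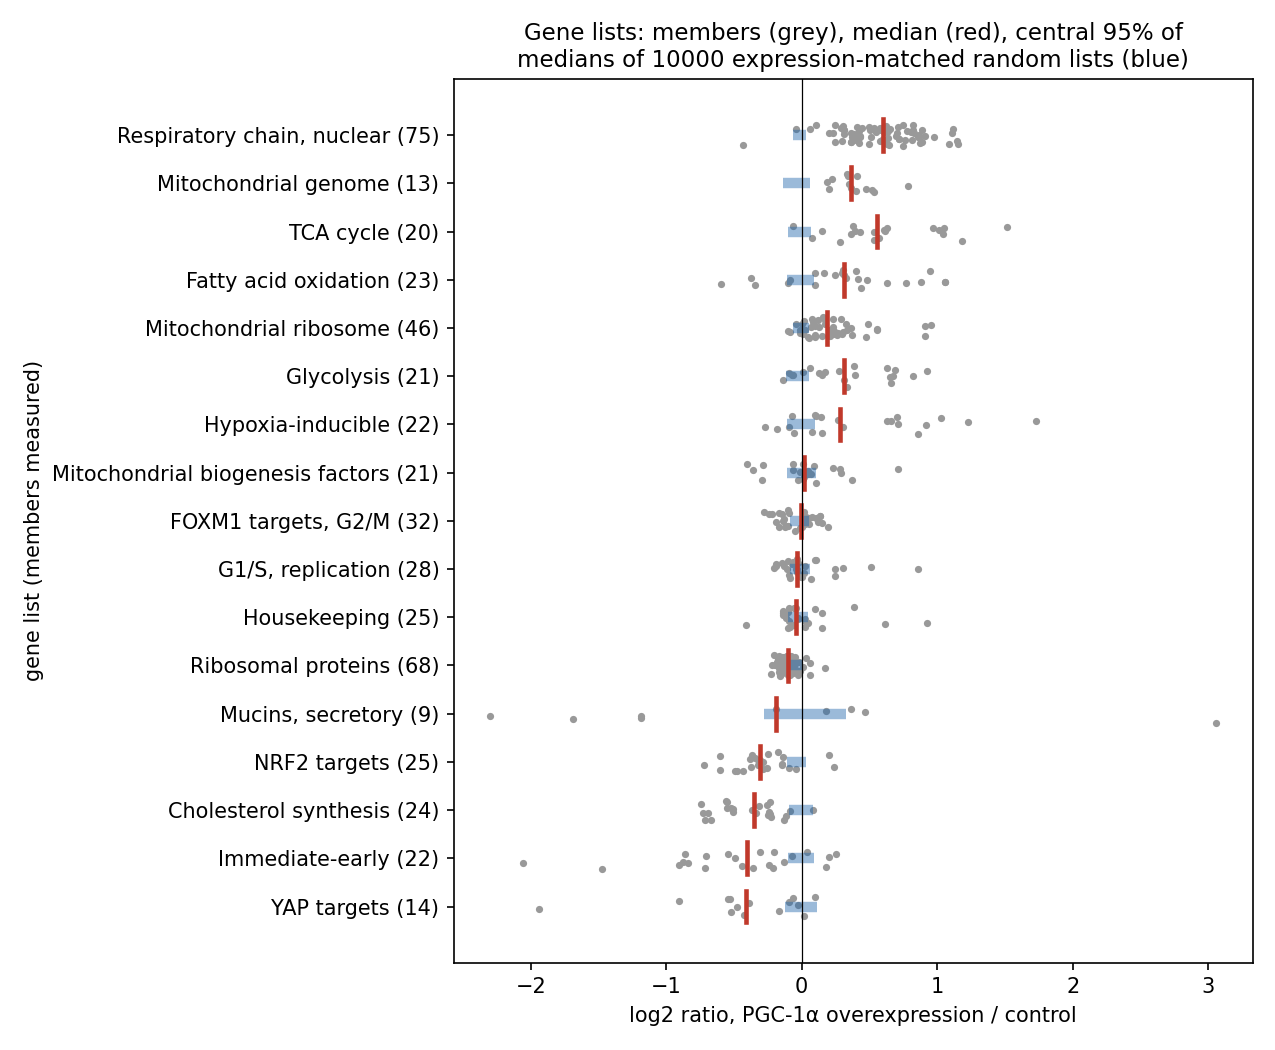
Log2 ratios of the PGC-1α library over the control for the members of 17 gene lists (grey points, 1 library per group), with each list's median (red line) and the central 95% of medians of 10000 random lists matched on mean expression (blue bar). Respiratory chain genes centre on 0.60 and the TCA cycle list on 0.55, FOXM1 targets on -0.01, and immediate-early genes on -0.40.

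Among stress and inflammatory lists the differences were smaller or mixed. For interferon-stimulated genes, 17 of 29 were measured, IFIT1 at -1.90, IFIT2 at -1.19 and IFIT3 at -0.68 were lower and IFIH1 was higher at 0.67, with a median of -0.11 at percentile 10.8. The IFIT genes overlap LIPA on the opposite strand, which is far more abundant and stood at -0.40, so their values are uncertain. Of 19 NF-κB targets, IL32 at 1.09 and SOD2 were higher and CCL2 at -0.93 was lower; the median of -0.12 lay at percentile 2.46, the mean was 0.02, and with lists matched on GC content the percentile was 3.45. Of 15 TGF-β targets, PMEPA1 at 0.88 and COL1A1 were higher and CTGF and TGFB2 at -0.68 lower. Their median of 0.19 lay at percentile 99.9, and its interval of -0.02 to 0.38 included 0. Of 23 ATF4 targets, NUPR1 at -1.38 and ATF3 at -0.71 were lower and DDIT3 higher at 0.60, with a median of 0.03 at percentile 83.4 and a mean of -0.005. None of 20 genes of the unfolded protein response was 1.5-fold apart. The most expressed were CANX at 0.10, HSPA5 at -0.11, CALR at -0.38 and HSP90B1 at -0.08, and the median of -0.11 lay at percentile 2.30, or 3.06 with lists matched on gene length. None of 13 heat shock genes was 1.5-fold apart, with a median of 0.01 at percentile 80.9; the most expressed were HSP90AA1 at -0.09, HSP90AB1 at -0.06, HSPA8 at -0.15 and HSPD1 at 0.31.

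For reference genes and other cell types, 2 of 25 housekeeping genes passed 1.5-fold, GPI at 0.93 and SDHA at 0.61, which also belong to glycolysis and the respiratory chain, and the median was -0.04 at percentile 43.1 with a mean of 0.03. Replication histones, whose mRNAs mostly lack a poly(A) tail, had 10 of 20 genes measured. HIST2H2AC at -1.10, HIST2H2BE at -0.80 and HIST1H2AG at -0.79 were lower, and the median was -0.36 (-0.80 to 0.10) at percentile 0.39. HIST2H2AC was added to the list after values had been seen, has near-identical copies and is uncertain, with a log2 ratio of -0.79 when they are summed. Without it, the median of 9 genes was -0.27 at percentile 2.31, or 3.27 with lists matched on gene length. Of 21 alveolar and airway genes, 6 were measured, SOX2 was lower at -0.92 and the median was -0.001 at percentile 49.6. Few markers of other cell types were measured. Of 12 fibroblast markers 4 were, with COL1A1 higher, a median of -0.03 at percentile 42.7 and a mean of 0.09. Of 12 immune markers 2 were, with CD14 lower at -0.82 and a median of -0.17 at percentile 28.4. Of 10 endothelial markers 1 was, ESAM at -0.14 and percentile 30.4. Of 12 markers of HEK293, a kidney-derived line often used to package viruses, 8 were measured and 1, NEFL, was higher, with a median of 0.03 at percentile 61.0.

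In all, 11 of the 34 lists had medians above the central 95% of their random lists and 9 below it. Chance would give 1.7 if the genes within a list varied independently of each other, as in the random lists. Lists share members and their genes are co-regulated, so these percentiles describe the 2 libraries and not a test between conditions. The log2 ratios from counts and from the authors' FPKM correlated across the 14154 genes with Pearson's r of 0.984 and Spearman's rho of 0.999, and 412 of 412 called genes had the same sign. Genes are not independent replicates, and the FPKM values were a rescaling of the same counts.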

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

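The coefficient of variation of 0.4, the 4-fold threshold, the FPKM over the genes measured by CPM, the histones without HIST2H2AC, the summed copies and the GC-matched lists were chosen after seeing the data. Among 1433 recomputed values, 12 list medians changed sign, over 4 lists whose main medians lie within the range of random lists: heat shock, epithelial junctions, HEK293 markers and REST targets. The main counts of 248 higher and 164 lower genes became 789 and 486 without a low-count filter, 104 and 53 with a mean of at least 5 CPM, 162 and 97 with FPKM, a pseudocount of 0.1 and a mean of at least 1 FPKM, and 98 and 39 with a pseudocount of 1 and that filter. Over the genes measured by CPM they were 176 and 119, and 65 and 28. They became 61 and 28 with an assumed coefficient of variation of 0.4 and 39 and 16 at 4-fold, where more or fewer genes pass by construction. They stayed within 1.5 times of the main counts under DESeq2 size factors (236 and 174), total count (241 and 172), upper quartile (243 and 170), 5 added counts (224 and 128), a coefficient of variation of 0.2 (237 and 155), protein-coding genes alone (209 and 121) and summed copies (238 and 153). These other scalings shifted all ratios by -0.01 to -0.02. The log2 ratio of PPARGC1A was 7.24 with FPKM and a pseudocount of 0.1 and 4.19 with a pseudocount of 1. A pseudocount pulls ratios of genes with a low FPKM toward 0. For 175 genes followed, 986 values stayed within the counting interval and 64 left it, 57 of these with a pseudocount of 1. Among 39 lists with at least 6 measured members, 273 medians stayed within their interval and 1 left it, the REST targets, from 0.05 to -0.23 with a mean of at least 5 CPM. That filter also took mucins from -0.19 to -1.19, hypoxia-inducible genes from 0.28 to 0.15 and creatine genes from 1.03 to 0.56; it leaves fewer members, and the cause was not tested further. List percentiles stayed within or outside the central 95% in 76 recomputations and changed in 3, for the unfolded protein response and NF-κB targets. Without HIST2H2AC the replication histones lay at percentile 2.31. With lists matched as well on gene length or GC content, which that tally leaves out, they lay at 3.27 and 2.91. Both values are inside the central 95%, so this list changed too. No paired analysis was possible because each group has 1 library, and no library could be left out. Depth limited MUC1, with 52 and 64 counts, whose interval of -0.08 to 1.03 covers both no difference and about 2-fold.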

Other observations

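The lists in this part, the tests on short mRNAs, HEK293 markers and GC-matched lists, and the summing of copies were chosen after values had been seen, so the percentiles here are not independent evidence. Some genes in further lists of mitochondrial metabolism were higher in the PGC-1α library, while most members of these lists were under 1.5-fold. The malate-aspartate shuttle, which carries reducing equivalents into mitochondria, had 3 of 7 genes at least 1.5-fold higher and none lower: the cytosolic aspartate aminotransferase gene GOT1 at 2.08 (1.99 to 2.17), the carrier gene SLC25A12 at 1.02 and MDH1 at 0.69. SLC25A12 overlaps the more abundant HAT1, so its counts are uncertain. The shuttle list's median log2 ratio of 0.39 exceeded those of 9997 of 10000 random lists, but its interval of -0.04 to 2.08 included 0. Mitochondrial carriers had 4 of 34 genes higher, among them SLC25A4 at 1.10, SLC25A12 and SLC25A5 at 0.59, and a median of 0.19 above all 10000 random lists. For mitochondrial protein import, TIMM44 at 0.67 and CHCHD4 at 0.63 were higher and TOMM5 at -0.62 lower among 29 genes, with a median of 0.22 at percentile 99.99. Respiratory chain assembly factors had COX10 at 0.80 and NDUFAF4 at 0.65 higher among 37, with a median of 0.10 at percentile 99.3. Branched-chain amino acid catabolism had ACADSB higher at 0.61 among 20, with a median of 0.23 at percentile 99.99.

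Creatine kinases, which buffer ATP, were among the larger differences, and their list was composed after CKMT1A and CKMT1B had been seen. CKB had 1343 counts in the control and 3383 in the PGC-1α library, 2.84-fold higher. The mitochondrial kinase genes CKMT1A and CKMT1B are near-identical copies, and together they had 19 and 242 counts, a log2 ratio of 3.81 (3.17 to 4.60). Of 6 measured creatine genes 3 were higher, both copies included, with a median of 1.03, or 0.56 with a mean of at least 5 CPM. As the list was composed from genes seen to be high, its place among random lists shows nothing. Among epithelial junction genes, 4 of 25 were lower, KRT19 at -1.13, JUP at -0.93, CLDN2 at -0.87 and TJP3 at -0.82, and 1 was higher, DSC2 at 0.64, with CLDN2 overlapping the more abundant MORC4, and with a median of 0.01 at percentile 74.97 and a mean of -0.08. KCNJ2, an inward rectifier potassium channel gene singled out after its values were seen, had 63 counts in the control and 1 in the PGC-1α library, a log2 ratio of -5.23 (-11.13 to -3.27).

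Respiratory chain genes, with a median of 0.60, were set against biases of the libraries. Among random lists matched on gene length the median stayed at percentile 100, and among lists matched on transcript GC content at percentile 100, which argues against either bias as the whole cause. A shift of short abundant mRNAs would carry the cytosolic ribosomal protein genes along, and their median was -0.1038, below the interval of 0.50 to 0.64. A hypothesis consistent with these tests is that the difference follows PGC-1α, but a difference between the 2 cultures or library preparations stays open, since 1 library per group cannot separate it.

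CEND1 and NEFL, genes known from neurons, ranked among the 10 highest; no list of neuronal genes was fixed beforehand, so no such theme is claimed. RNA of HEK293 packaging cells could bring NEFL, which was 28.1-fold higher. In sum, 6 other HEK293 markers under 5 CPM in the control had 251 and 278 counts, a normalised ratio of 1.2479 (1.05 to 1.49). This sum is weighted toward the markers with most counts. Of the markers below the filter, NEFM had 8 and 20 counts, PAX2 4 and 9, CRABP1 4 and 2, and POU3F2 0 and 0. These are too few to decide, so a small amount of such RNA is not excluded. Loss of repression by REST, a silencer of neuronal genes, remains open: of 34 measured REST targets, in a list composed after HCN3 had been seen, 9 were higher and 3 lower. Their median of 0.05 (-0.20 to 0.40) lay at percentile 74.39, not past the upper bound set in advance, but its interval holds the upper limit of random lists, 0.15, a condition added once the percentile was known. With a mean of at least 5 CPM that median was -0.23, and REST itself had a log2 ratio of -0.06 (-0.19 to 0.07).

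Genes with a near-identical copy made up 25 of the 412 called genes, or 6.07%, against 3.46% of all measured genes. When the counts of copies were summed, 24.0% of them, 6 of 25, stayed 2-fold apart, BOLA2B, NPY4R, NPY4R2, SERF1B, CKMT1A and CKMT1B. These are not independent, since NPY4R and NPY4R2 share the same sum, as do CKMT1A and CKMT1B. Among the genes that fell under 2-fold, GOLGA8K and GOLGA8T also share a sum. CBSL, an example picked after its values were seen, had 80 and 4 counts alone, but 401 and 231 with its copy. Reads assigned to different copies in the 2 libraries may therefore account for most of these calls, although summing would also dilute a true difference in 1 copy beside an abundant one, and the counts cannot tell these apart. No biological explanation was tested for this pattern.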
